A study of Mus musculus with 19 samples.

How the data were processed

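The authors deposited 1 table of 24537 genes with values named as TPM for 19 libraries, which was the only data analysed here. Per the submitters' processing notes, base calls were made with bcl2fastq 2.20, quality was summarised with MultiQC 1.0, reads were aligned to mm10 with STAR 2.5.3a, and TPM was computed with HOMER 4.10.4. Whether reads were counted over exons or whole gene bodies, and on which strand, is not given in the sources used here. The deposited TPM sum to 684004 in the median library. Because TPM keeps no read counts, no count model was used and read depth is unknown. Raw reads were not analysed here, so neither the Fmr1 insertion nor the floxed part of Smad4 was read from sequence.

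Each library was divided by a median-of-ratios factor over genes with a mean TPM of at least 1, and log2(scaled TPM + 1) was analysed for the 15049 genes past that filter. limma-trend fitted all 19 libraries of the 4 groups together, with group as the only term, and gave 5 comparisons and the interaction, (double mutant minus Fmr1 KO) minus (Smad4 cKO minus WT). Benjamini-Hochberg adjustment was made within each comparison, and genes passed at an adjusted p under 0.05; every adjusted p of a gene comes from limma. Targeted genes were also tested by exact permutation of the libraries of both groups. Gene positions came from GENCODE vM21 on GRCm38, matched by symbol for 14644 of 15049 tested genes (97.3%). The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.

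Genes were named by a rule. It took Fmr1 and Smad4 throughout, and in each comparison up to 12 higher and 12 lower genes with the smallest adjusted p among those that passed. Where fewer than 10 passed, it took 5 higher and 5 lower with the smallest p. It also took up to 4 members of each gene list with the smallest p, and Bmp6, Bmp4, Id1, Id3, Gfap, Gpc6 and Chrdl1 wherever measured. Clone, predicted, microRNA and small nucleolar RNA names were counted but passed over in naming. Of the genes this rule and the lists gave, 3 are not reported here by name, and they stay in all counts, list tests and adjusted p.

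Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of each comparison and at least 5 members past the filter. The 24 lists tested were SMAD-responsive targets, BMP and TGF-beta pathway genes, mature astrocyte markers, reactive astrocyte genes, astrocyte synapse regulators, transmitter uptake and ion homeostasis, and extracellular matrix. They also held cholesterol synthesis and export, glycolysis and lactate shuttle, oxidative phosphorylation, antigen presentation and interferon response, FMRP-bound transcripts, circadian clock genes, immediate early and dissociation genes, cytoplasmic ribosomal protein genes, and cell cycle genes. The others were markers of neurons, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells, mural cells and fibroblasts, ependymal and choroid plexus cells, and neural progenitors. The mitochondrially encoded list had 0 of 13 members past the filter and was not tested. A list's score in a library is the mean of its members' log2 values, each centred over the libraries. Scores of 9 cell-type lists were compared by exact permutation within Smad4 genotypes and within days.

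The correlation of effects across genes was set against 100 draws of the genotype labels within each background. The reversal of the Fmr1 effect was set against 100 draws of unchanged groups. These were made from whole libraries of residuals about their group means. Lists, naming rule, tests and most alternatives were fixed before the data were examined. The alternatives were TPM without scaling, quantile normalization, pseudocounts of 0.1 and 0.5, a mean TPM of at least 5 and no filter. They also were a block for replicate number, postnatal day as a number, a fit of the compared groups alone, library weights, no variance trend, a threshold of 0.1, and 19 fits each without 1 library. Alternatives added after seeing the data were 3 cell-type scores as covariates, postnatal day as a factor, leaving out the library of highest neuron score in each group, and leaving out microRNA and small nucleolar RNA genes.

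The procedure was tested on simulated data with 200 of 15049 genes changed. In Smad4 cKO against WT it recovered 46% of genes changed by 1.41-fold, 74% at 2-fold, 92% at 4-fold and 96% at 8-fold, with 8 false calls. In Fmr1 KO against WT it recovered 40%, 78%, 94% and 96%, with 13 false calls, and in the interaction 22%, 56%, 88% and 98%, with 8 false calls. A shifted list was called by camera (adjusted p = 9.96e-39) and 0 of the other lists were. Simulated genes were drawn independently of each other. The camera result therefore does not cover lists with correlated members, such as endothelial markers at an estimated correlation of 0.79.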

Results

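Nuclear RNA of cortical astrocytes was sequenced from 19 libraries of mice aged postnatal day 26 to 28. Nuclei had been sorted for SOX9, an astrocyte transcription factor, and against NEUN, a neuronal nuclear protein. The libraries fell into 4 genotypes: WT (n = 4), Smad4 cKO (n = 6), Fmr1 KO (n = 5) and the double mutant with both (n = 4). Fmr1 encodes FMRP, the RNA-binding protein lost in fragile X syndrome. Smad4 encodes the common SMAD that carries BMP and TGF-beta signals to the nucleus, and a Gfap-driven Cre removes a floxed part of it in astrocytes. Day 26 held 8 libraries, day 27 held 9 and day 28 held 2. WT had 1, 2 and 1 libraries on the days in that order and Smad4 cKO 3, 2 and 1. Fmr1 KO had 2, 3 and 0, and the double mutant 2, 2 and 0. The table lists 24537 genes as TPM, a length-scaled abundance. Read totals are therefore unknown, and no counting interval can be given. The listed values sum to between 665382 and 716222 per library, with a median of 684004, so they do not hold all of a library's TPM. What the rest belongs to is not given in the sources used here. Between 17513 and 18692 genes were above 0 in a library. Rn45s, the ribosomal RNA precursor, took from 15.6% to 35.7% of the listed TPM. Its means were 29.2% ± 6.4 (SD, n = 4) in WT, 26.1% ± 5.1 (n = 6) in Smad4 cKO, 19.7% ± 2.6 (n = 5) in Fmr1 KO and 18.6% ± 3.6 (n = 4) in the double mutant. Scaled TPM below is TPM divided by a library factor between 0.918 and 1.066, and changes are log2 differences of scaled TPM plus 1, with their standard error (SE).

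The transcripts of both targeted genes came first, as a check of the labels. Fmr1 (chromosome X, 68678541 to 68717963, build GRCm38) was higher in the libraries labelled Fmr1 KO. Its scaled TPM was 26.2 ± 4.29 (SD, n = 4) in WT, 23.9 ± 2.73 (n = 6) in Smad4 cKO, 38.9 ± 1.94 (n = 5) in Fmr1 KO and 37.1 ± 1.37 (n = 4) in the double mutant. The highest of the 10 libraries labelled Fmr1 intact reached 31.6, and the lowest of the 9 labelled Fmr1 KO was 35.5. Exact permutation of the 2 groups gave p = 0.00794 for Fmr1 KO against WT and p = 0.00476 for the double mutant against Smad4 cKO, each the smallest that these group sizes allow. The difference was 0.51 on day 26 (4 labelled KO, 4 labelled intact) and 0.71 on day 27 (5 and 4). Over all genes, the rise of Fmr1 passed in the double mutant against Smad4 cKO (log2 0.62 ± 0.09, adjusted p = 0.0154) and not in Fmr1 KO against WT (0.57 ± 0.10, adjusted p = 0.0835). Smad4 (chromosome 18, 73639009 to 73703780) was listed at 33.3 ± 2.62 (SD, n = 4) in WT, 32.4 ± 2.24 (n = 6) in Smad4 cKO, 32.4 ± 1.49 (n = 5) in Fmr1 KO and 32.2 ± 2.68 (n = 4) in the double mutant. Exact permutation gave p = 0.538 for Smad4 cKO against WT and p = 0.857 for the double mutant against Fmr1 KO. A gene-level value does not resolve the insertion in Fmr1 or the floxed part of Smad4. Neither allele can be read from these data, and the libraries are named by their labels throughout. Without Smad4 cKO replicate 2 or any 1 of the 4 double mutant replicates, Fmr1 no longer passed against Smad4 cKO. Nor did it with a replicate block, the compared groups alone, cell-type scores in the model, or the libraries of highest neuron score left out. Its adjusted p ranged from 0.00489 to 0.404 over all alternatives.

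**Figure D1:**
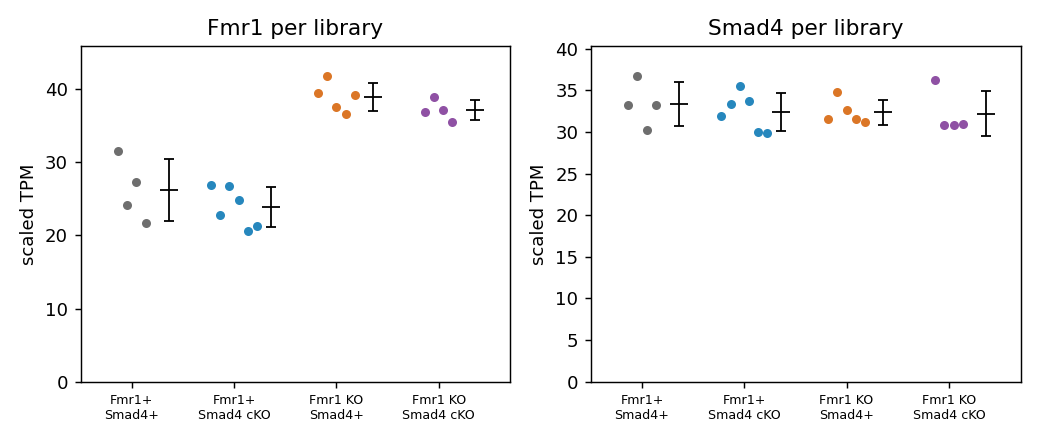
Scaled TPM of Fmr1 (left) and Smad4 (right) in each of the 19 libraries, by genotype, with the mean and SD as bars. All 9 libraries labelled Fmr1 KO lie above 35 for Fmr1 and all 10 others below 32, while the 4 genotypes overlap for Smad4.

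Smad4 cKO against WT compares libraries by the Smad4 label with Fmr1 labelled intact. Pmepa1, a TGF-beta-induced inhibitor of SMAD signalling, rose the most by adjusted p, from 19.4 ± 4.19 scaled TPM (SD, n = 4) to 138 ± 16.7 (n = 6), a log2 change of 2.79 ± 0.15 (SE). Other genes rose with it. The heparan sulfate proteoglycan Sdc3 rose by 1.55 ± 0.11, Scube1 by 1.54 ± 0.17, the secreted chitinase-like Chil1 by 1.67 ± 0.19 and the latent TGF-beta binding protein Ltbp3 by 0.88 ± 0.10. Among the genes that fell, Myoc, which encodes myocilin, went from 20.3 ± 1.90 (n = 4) to 1.00 ± 0.665 (n = 6), a log2 change of -3.47 ± 0.21. Id3, a BMP target that blocks bHLH factors, fell by 2.24 ± 0.20, the bHLH factor Atoh8 by 2.69 ± 0.19, the matrix glycoprotein Tnc by 1.98 ± 0.18 and the receptor-regulated SMAD Smad9 by 1.36 ± 0.18. In all, 118 of 15049 genes passed, 79 higher and 39 lower, 35 of them by over 2-fold. In total 1246 had an unadjusted p under 0.05 where chance gives 752.

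Other named genes of this comparison rose or fell as well. Plekhd1 rose by 1.64 ± 0.18, Pnpla3, a lipid droplet protein, by 1.16 ± 0.15, and Ldlrad4, which restrains TGF-beta signalling, by 0.98 ± 0.12. Ap3s1 (0.78 ± 0.08), Rimklb (0.72 ± 0.09), the BMP receptor Acvr1 (0.62 ± 0.08) and Prrt1 (0.61 ± 0.08) rose too, each with an adjusted p of 0.000537 or below. Serpinf1 fell by 1.88 ± 0.26, Inpp5j by 1.36 ± 0.19, Ppp3r2 by 1.16 ± 0.18, and Ddit4l by 1.12 ± 0.13. So did Btbd3, by 1.1 ± 0.11, the homeodomain-only protein gene Hopx by 0.99 ± 0.14 and the corepressor Tle2 by 0.73 ± 0.10. Of these 24 named genes, 23 kept their call in each of 14 alternatives and 19 fits without 1 library. Serpinf1 kept its call in the 13 alternatives that tested it and the same 19 fits, and was not tested with a mean TPM of at least 5. Pmepa1 lies on chromosome 2 (173224458 to 173276533), Sdc3 on chromosome 4 (130792537 to 130826319), Myoc on chromosome 1 (162639155 to 162649693), and Id3 on chromosome 4 (136143497 to 136145755). Atoh8 lies on chromosome 6 (72206177 to 72235577), Tnc on chromosome 4 (63959785 to 64047015) and Smad9 on chromosome 3 (54755582 to 54801257), all protein-coding in GRCm38. Within a day, Smad4 cKO and double mutant libraries against the others gave Pmepa1 2.74 on day 26 (5 and 3 libraries) and 3.04 on day 27 (4 and 5), Myoc -3.02 and -3.15, Id3 -2.21 and -2.06, and Tnc -1.92 and -1.84. With day as a factor, 119 genes passed, 102 of them among the 118. With a replicate block 63 did, with the compared groups alone 62, and with the libraries of highest neuron score left out 64.

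Of 16 measured SMAD-responsive targets, 2 rose and 4 fell, and 8 passed when adjusted over the list alone. Pmepa1, Id3, Atoh8 and Smad9 are given above. Skil, a SMAD corepressor, rose by 0.76 ± 0.16 and the homeobox gene Msx2 fell by 1.1 ± 0.23. Id1 was at -1.15 ± 0.31 (adjusted p = 0.122) and Id4 at -0.83 ± 0.19 (adjusted p = 0.0577). Skil, Msx2 and Id4 lie outside the naming rule here, and each was chosen after its values were seen. The list as a whole stood lower than other genes, with a median of -0.36 and a camera adjusted p of 0.00186, and adjusted p = 0.456 with an estimated correlation. Of the 28 ligands, receptors and SMADs of the BMP and TGF-beta pathways, Acvr1 alone passed, 2 passed when adjusted over the list alone, and the receptor Bmpr1a was at -0.28 ± 0.07 (adjusted p = 0.0701). Bmp6 was at -0.11 ± 0.24 and Bmp4 at -0.20 ± 0.61. The calls of Skil and Msx2 were each lost in several fits. Skil lost its call without WT replicate 1, 3 or 4 or Smad4 cKO replicate 1, 3 or 5 (adjusted p over all alternatives 0.0137 to 0.122). It also lost it in 7 of 14 other alternatives, among them TPM as deposited, day as a number or a factor and library weights. Msx2 lost its call without WT replicate 1, 2 or 3 or any Smad4 cKO replicate (0.0101 to 0.242), and in 5 of 13 other alternatives, among them quantile normalization and a replicate block. Without WT replicate 4, Id1 passed at -1.40.

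**Figure D2:**
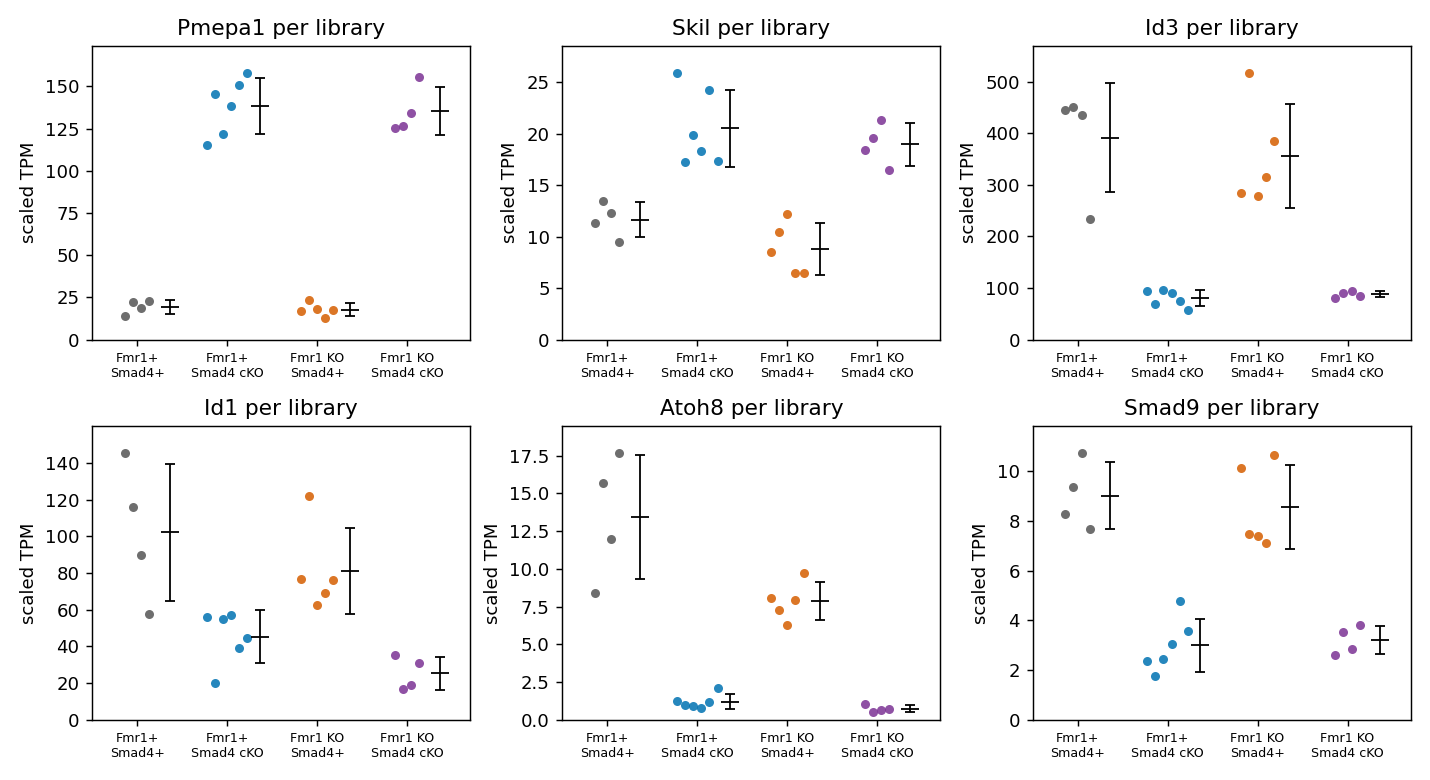
Scaled TPM of 6 SMAD-responsive genes in each library, by genotype, with the mean and SD as bars. Pmepa1 and Skil are higher and Id3, Atoh8 and Smad9 lower in both genotypes with the Smad4 cKO label. Id1 passed in the double mutant against Fmr1 KO and against WT and not in Smad4 cKO against WT.

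Genes of astrocyte function were read as lists. Of 20 mature astrocyte markers, the potassium channel Kcnj10 rose, by 0.74 ± 0.14 (adjusted p = 0.01), and 3 passed when adjusted over the list alone. The transporter Slc7a10 was at 0.60 ± 0.15 (adjusted p = 0.0847) and the water channel Aqp4 at -0.80 ± 0.23 (adjusted p = 0.141). The list's median was 0.15, with a camera adjusted p of 0.0228 and adjusted p = 0.749 with an estimated correlation. Of 24 genes of transmitter uptake and ion homeostasis, Kcnj10 and the glycine transporter Slc6a9 (0.76 ± 0.15, adjusted p = 0.0176) rose, 5 passed when adjusted over the list alone, and the list did not pass (median 0.02, adjusted p = 0.176). None of 20 synapse regulators passed (median 0.07, adjusted p = 0.148) and 2 did when adjusted over the list alone. Sparc was at 1.38 ± 0.33 (adjusted p = 0.0613), Lrp1 at 0.30 ± 0.09 and Chrdl1 at 0.10 ± 0.18. Of 29 extracellular matrix genes Tnc alone passed, and 4 did when adjusted over the list alone. Timp3 was at 0.55 ± 0.14 (adjusted p = 0.1). None of 22 reactive astrocyte genes passed (median -0.23, adjusted p = 0.125), and 1 did when adjusted over the list alone. Gfap was at 0.85 ± 0.32 (adjusted p = 0.379) and C4b at 1.32 ± 0.32 (adjusted p = 0.0724). The 24 genes of cholesterol synthesis and export stood higher, 23 of them above 0 with a median of 0.28, although no member passed, over all genes or over the list alone. Their camera adjusted p was 4.75e-07, and adjusted p = 0.749 with an estimated correlation. Neuron markers stood lower in the same comparison, with a median of -0.49 over 20 genes (camera adjusted p = 0.00241; adjusted p = 0.749 with an estimated correlation). Without WT replicate 2, with a replicate block or with cell-type scores in the model, Kcnj10 and Slc6a9 no longer passed. Nor did Kcnj10 with the compared groups alone, or Slc6a9 with the libraries of highest neuron score left out. Over all alternatives their adjusted p ranged from 0.00478 to 0.0771 and from 0.00433 to 0.0894. With the 4 libraries of the highest neuron score left out, 1 of each genotype, 64 genes passed.

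The double mutant against Fmr1 KO makes the same comparison in the libraries labelled Fmr1 KO. Pmepa1 rose again, from 17.7 ± 3.82 scaled TPM (SD, n = 5) to 136 ± 14.1 (n = 4), a log2 change of 2.89 ± 0.16 (SE). So did Scube1 (1.57 ± 0.18), Sdc3 (1.40 ± 0.12), Plekhd1 (1.41 ± 0.19) and Ldlrad4 (0.91 ± 0.13). Myoc fell from 13 ± 2.96 (n = 5) to 0.758 ± 0.270 (n = 4), a log2 change of -2.98 ± 0.22. Atoh8 fell by 2.35 ± 0.20, Id3 by 1.97 ± 0.21, Tnc by 1.61 ± 0.18 and Hopx by 1.38 ± 0.15. Of 15049 genes 61 passed, 29 higher and 32 lower, 26 of them by over 2-fold. In total 825 had an unadjusted p under 0.05 where chance gives 752. Skil (1.06 ± 0.17), Scel (1.23 ± 0.20), Rasl10b (1.15 ± 0.19), Pnpla3 (1.03 ± 0.16), Ltbp3 (0.66 ± 0.10), Ap3s1 (0.60 ± 0.09) and the receptor Notch3 (0.54 ± 0.09) rose, each with an adjusted p of 0.00701 or below. Smad9 fell by 1.18 ± 0.19, Ptchd2 by 1.15 ± 0.20, Ddit4l by 0.88 ± 0.13, Sned1 by 0.86 ± 0.13, the mitochondrial glutamate carrier Slc25a18 by 0.84 ± 0.15, Tle2 by 0.81 ± 0.11 and Sorbs3 by 0.39 ± 0.07. Of 27 genes named as passing here, including Acvr1, Sparc and Id1, 12 kept their call in each of 14 alternatives and 19 fits without 1 library. Those 12 were Pmepa1, Sdc3, Scube1, Ldlrad4, Myoc, Atoh8, Id3, Hopx, Tnc, Tle2, Ddit4l and Sned1. In TPM as deposited, 47 passed, 29 higher and 18 lower, and with day as a factor 64 did, 55 of them among the 61. A replicate block gave 21, the compared groups alone 20, cell-type scores in the model 36 and library weights 91. Removing Fmr1 KO replicate 1, 3, 4 or 5 or any double mutant replicate moved the count to between 27 and 38. Leaving out the library of highest neuron score in each genotype moved it to 24.

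Gene groups were read in this background as well. Of 16 SMAD-responsive targets 2 rose and 4 fell, and 7 passed when adjusted over the list alone. Id1 was among those that fell, by 1.67 ± 0.32 (adjusted p = 0.0294). The list's median was -0.15, with a camera adjusted p of 0.0270, and adjusted p = 0.971 with an estimated correlation. Acvr1 rose by 0.45 ± 0.09 (adjusted p = 0.0262), 1 of 28 pathway genes, with 4 passing when adjusted over the list alone. Sparc, a matricellular protein that limits synapse formation, rose by 1.81 ± 0.34 (adjusted p = 0.0255), from 27.9 ± 17.8 (SD, n = 5) to 90.4 ± 19.3 (n = 4). It was the 1 of 20 synapse regulators that passed, over all genes and over the list alone. Cholesterol genes again stood higher, 22 of 24 above 0 with a median of 0.17 and no member passing. The camera adjusted p was 0.0270, and adjusted p = 0.971 with an estimated correlation. Oligodendrocyte markers stood higher as well, with a median of 0.67 over 15 genes and no member passing (camera adjusted p = 0.0270; adjusted p = 0.971 with an estimated correlation). Gfap was at 0.73 ± 0.33 (adjusted p = 0.85), Chrdl1 at -0.07 ± 0.19, Gpc6 at -0.03 ± 0.09, Bmp6 at -0.15 ± 0.25 and Bmp4 at 0.30 ± 0.63. Acvr1, Sparc, Id1, Slc25a18 and Sorbs3 each lost their call without Fmr1 KO replicate 4 and without Fmr1 KO replicate 5. Acvr1 lost it without any of 8 libraries, Id1 of 7, Sparc and Sorbs3 of 6 and Slc25a18 of 4, all of them Fmr1 KO or double mutant. All 5 also lost it with a replicate block, with the compared groups alone, and with the libraries of highest neuron score left out. Acvr1 and Slc25a18 lost it with cell-type scores in the model too, and Sorbs3 in TPM as deposited. Their adjusted p over all alternatives reached 0.268, 0.373, 0.167, 0.147 and 0.146 in that order.

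Of the 61 genes called by the Smad4 label in libraries labelled Fmr1 KO, 49 were also called in libraries labelled Fmr1 intact. The comparisons share no library, but both take each gene's spread from the same fit. In both, 26 genes were higher where independent calls would give 0.15, 23 were lower where they would give 0.08, and 0 were opposite. As the calls are not independent, these chance values may be too low. Pmepa1, Sdc3, Scube1, Skil and Acvr1 are among the 26, and Myoc, Atoh8, Id3, Tnc, Smad9 and Hopx among the 23. Of 130 genes called in either, 69 passed in libraries labelled Fmr1 intact alone and 12 in libraries labelled Fmr1 KO alone. All 118 and all 61 had the same sign in the other background. The interaction, the test of the difference itself, called 0 genes by limma, with 250 at an unadjusted p under 0.05 where chance gives 752. Inpp5j had the smallest p among named genes at 1.1 ± 0.28 (SE), and Btbd3 stood at 0.52 ± 0.16, both with an adjusted p of 1. Of the gene lists, 5 passed camera in the interaction. Neuron markers had a median of 0.57 (camera adjusted p = 0.00142), cell cycle genes 0.33 (0.00908), ribosomal protein genes 0.18 (0.00913), reactive astrocyte genes 0.25 (0.0200) and cholesterol genes -0.16 (0.0124). With an estimated correlation each had an adjusted p of 0.84 or above, and no member of them passed. With day as a factor the medians were 0.55, 0.31, 0.18, 0.25 and -0.11 in that order. Across 15049 genes, which are not independent replicates, both Smad4 effects correlated with Pearson's r = 0.259 and Spearman's rho = 0.289. Drawing the labels at random within each background 100 times gave a permutation p of 0.0297, 1 of 2 such relations computed. With a replicate block the permutation p was 0.188.

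**Figure D3:**
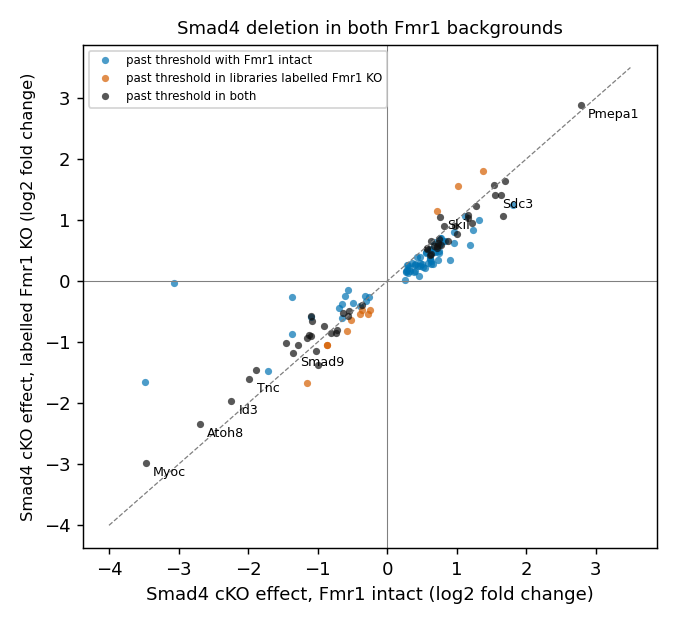
Log2 change by the Smad4 label in libraries labelled Fmr1 intact (horizontal) against libraries labelled Fmr1 KO (vertical), for the 130 genes past the threshold in either. Black points passed in both, 49 genes, and all points lie in the same-sign quadrants around the dashed line of equal change.

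Fmr1 KO against WT compares libraries by the Fmr1 label with Smad4 labelled intact. No gene passed by limma, with 1239 of 15049 at an unadjusted p under 0.05 where chance gives 752, and 8 passed at an adjusted p under 0.1. Among the genes with the smallest p were, on the higher side, Fmr1, the adenylyl cyclase Adcy2 at 0.58 ± 0.10 (SE), the matrix protease Adamts5 at 0.50 ± 0.09 and Nim1k at 0.54 ± 0.12. On the lower side were the calcium pump Atp2a3 at -1.09 ± 0.20, Grasp at -1.08 ± 0.19, Sh2d3c at -1.06 ± 0.19, Rnf144b at -0.95 ± 0.17 and Jade2 at -0.60 ± 0.10. Their adjusted p ranged from 0.0835 to 0.151. Kcnj10 was at 0.65 ± 0.14 (adjusted p = 0.151). The secreted BMP antagonist Chrdl1 was at 0.68 ± 0.19 (adjusted p = 0.211), with 28.6 ± 7.36 scaled TPM (SD, n = 5) against 17.1 ± 2.01 (n = 4). Gfap was at -0.51 ± 0.33, Bmp6 at -0.22 ± 0.25, Bmp4 at -0.12 ± 0.63, Id1 at -0.29 ± 0.32, Id3 at -0.13 ± 0.21 and Gpc6 at 0.13 ± 0.09. Without WT replicate 3, 164 genes passed, 17 higher and 147 lower. Among the lower were 12 of the 15 endothelial markers. WT replicate 3 has the lowest endothelial score of the 4 WT libraries, so leaving it out widens that difference by itself. Without the library of highest neuron score in each genotype, which leaves out the same WT library, 84 passed, 13 higher and 71 lower. Without WT replicate 1 or Smad4 cKO replicate 3 a single gene did.

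Blood vessel markers stood lower in the libraries labelled Fmr1 KO. All 15 endothelial markers stood lower in Fmr1 KO than in WT, with a median of -1.19, and 14 passed when adjusted over the list alone, against 0 over all genes. The camera adjusted p was 8.47e-20, and adjusted p = 0.155 with an estimated correlation. Flt1, the VEGF receptor, was at -1.33 ± 0.35 (SE), Egfl7 at -1.41 ± 0.37, the endothelial phosphatase Ptprb at -1.22 ± 0.28 and the drug exporter Abcb1a at -1.30 ± 0.34. Over all 19 libraries, the mean endothelial score was -0.53 ± 0.32 (SD) in the 9 labelled Fmr1 KO and 0.48 ± 0.52 in the 10 others. Exact permutation gave p = 0.000302 within Smad4 genotypes and p = 0.000189 within day strata, or 0.00272 and 0.00170 adjusted over 9 marker lists. The day strata took days 26 and 28 together, so they do not hold the day fixed. Both day 28 libraries are labelled Fmr1 intact, with endothelial scores of 1.352 in WT replicate 2 and 0.577 in Smad4 cKO replicate 4. In single comparisons the score did not pass once adjusted. Exact permutation gave p = 0.0317 in Fmr1 KO against WT (adjusted p = 0.285), 0.00952 in the double mutant against Smad4 cKO (0.0857) and 0.114 against WT (0.342). The scores were -0.42 (n = 4) against 0.58 (n = 4) on day 26 and -0.62 (n = 5) against 0.12 (n = 4) on day 27. Mural and fibroblast markers stood lower as well, with a median of -0.58 over 11 genes (camera adjusted p = 0.00163; adjusted p = 0.451 with an estimated correlation). None passed, 1 did when adjusted over the list alone, and Abcc9 was at -0.82 ± 0.23. Over all libraries their score gave an exact permutation p of 0.0145 within Smad4 genotypes and 0.00869 within the same day strata, or 0.0652 and 0.0391 adjusted.

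**Figure D4:**
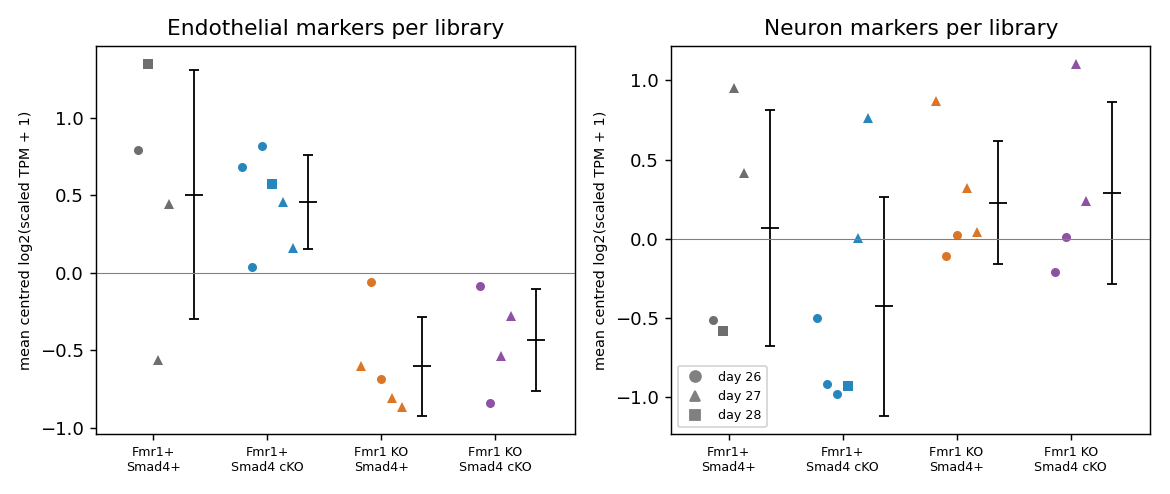
Mean centred log2 level of 15 endothelial (left) and 20 neuron (right) markers in each library, by genotype, with symbols for the postnatal day and bars for the mean and SD. The 9 libraries labelled Fmr1 KO all lie below 0 for endothelial markers, and 9 of 10 others above; the day 27 libraries lie at or above 0 for neuron markers.

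Reactive and metabolic gene groups also stood apart in Fmr1 KO, without any gene that passed. Of 22 reactive astrocyte genes 21 stood lower in Fmr1 KO than in WT, with a median of -0.61, and 10 passed when adjusted over the list alone, against 0 over all genes. The camera adjusted p was 5.03e-11, and adjusted p = 0.155 with an estimated correlation. Aspg was at -0.71 ± 0.19 (SE), Srgn at -0.78 ± 0.24 and the complement gene C4b at -1.05 ± 0.33. Mean reactive scores were 0.29 in WT, 0.16 in Smad4 cKO, -0.31 in Fmr1 KO and -0.15 in the double mutant. Endothelial scores ranked the groups alike, at 0.51, 0.46, -0.6 and -0.43 in that order. Whether both lists share a source was not tested. Of 24 cholesterol genes 23 stood higher, with a median of 0.27 and 0 passing (camera adjusted p = 1.15e-06; adjusted p = 0.534 with an estimated correlation). Among them Hmgcs1 was at 0.53 ± 0.25 and the regulator Srebf2 at 0.21 ± 0.06. Genes of transmitter uptake and ion homeostasis stood higher in 21 of 24, with a median of 0.14, 0 passing and 2 adjusted over the list alone (camera adjusted p = 5.76e-05; adjusted p = 0.372 with an estimated correlation). The glutamate receptor Grm3 was at 0.42 ± 0.12. Mature astrocyte markers had a median of 0.13 (camera adjusted p = 0.00330; adjusted p = 0.534 with an estimated correlation). Synapse regulators had one of 0.11, with Nrcam at 0.28 ± 0.10 (camera adjusted p = 0.00415; adjusted p = 0.185 with an estimated correlation). In each list 1 gene passed over the list alone. The 30 FMRP-bound transcripts had a median of 0.08 and did not pass (camera adjusted p = 0.0689), with 0 members passing over all genes and 1 over the list alone, Shank3 at -0.61 ± 0.16. Extracellular matrix genes had a median of -0.07 (adjusted p = 0.366), 2 passing over the list alone, with Col4a1, a vessel basement membrane collagen, at -0.85 ± 0.22. SMAD-responsive targets had a median of -0.13 and 0 members passing (camera adjusted p = 0.0416; adjusted p = 0.534 with an estimated correlation). The BMP and TGF-beta pathway genes had a median of 0.01 (adjusted p = 0.880). Oligodendrocyte markers stood higher, with a median of 0.62 (camera adjusted p = 0.0115; adjusted p = 0.662 with an estimated correlation). Microglia markers stood lower, with a median of -0.59 (camera adjusted p = 0.00437; adjusted p = 0.647 with an estimated correlation).

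The double mutant against Smad4 cKO compares libraries by the Fmr1 label with Smad4 labelled deleted. By limma 3 of 15049 genes passed, with 1138 at an unadjusted p under 0.05 where chance gives 752. Fmr1 rose by 0.62 ± 0.09 (SE). The small nucleolar RNA Snora34 rose by 2.34 ± 0.31, from 8.23 ± 4.03 scaled TPM (SD, n = 6) to 42.2 ± 3.5 (n = 4). The chromatin protein gene Jade2 fell by 0.63 ± 0.09, from 14.8 ± 1.92 to 9.12 ± 0.518. Snora34 lies outside the naming rule and was chosen after its values were seen, because the count is small. Other genes with a small p did not pass: Nap1l3 at 0.93 ± 0.17, Fam206a at 0.60 ± 0.13, the adhesion molecule Chl1 at 0.51 ± 0.11, and Map2 at 0.21 ± 0.04. Nor did Neat1 at -1.1 ± 0.22, Mapk12 at -0.68 ± 0.16, Zbtb46 at -0.64 ± 0.13 and Copz2 at -0.41 ± 0.09. Endothelial markers stood lower here too, 15 of 15 with a median of -0.93, 0 passing over all genes and 12 adjusted over the list alone. The camera adjusted p was 4.08e-15, and adjusted p = 0.524 with an estimated correlation. Egfl7 was at -1.35 ± 0.36, Flt1 at -1.33 ± 0.34, Slco1a4 at -1.43 ± 0.39 and Abcb1a at -1.14 ± 0.33. Reactive astrocyte genes stood lower in 18 of 22 with a median of -0.33, 0 passing and 1 over the list alone (camera adjusted p = 0.000142; adjusted p = 0.547 with an estimated correlation). Aspg was at -0.71 ± 0.18 and C4b at -1.01 ± 0.32. Neuron markers stood higher, all 20 with a median of 0.59, 0 passing and 2 over the list alone (camera adjusted p = 7.04e-07; adjusted p = 0.547 with an estimated correlation). Nefm was at 1.43 ± 0.39 and Sst at 2.06 ± 0.62. Each of the 4 double mutant replicates, when left out, took the count to 0. Leaving out Smad4 cKO replicate 2 took it to 1. With day as a factor 2 genes passed, and 0 did with the library of highest neuron score left out of each genotype.

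The double mutant against WT gave 144 calls of 15049 genes by limma, with 1801 at an unadjusted p under 0.05 where chance gives 752. Pmepa1 rose by 2.76 ± 0.16 (SE), Chil1 by 1.92 ± 0.21, from 16.5 ± 3.00 scaled TPM (SD, n = 4) to 65.9 ± 15.8 (n = 4), Scube1 by 1.58 ± 0.19, Sdc3 by 1.26 ± 0.12 and Kcnj10 by 0.99 ± 0.15. Myoc fell by 3.61 ± 0.23 and Atoh8 fell by 3.01 ± 0.21, as did Id3 by 2.10 ± 0.22, Id1 by 1.96 ± 0.34 and the nuclear non-coding RNA Neat1 by 1.5 ± 0.24. Of the 144, 74 were higher and 70 lower, and 36 differed by over 2-fold. Plekhd1 (1.55 ± 0.20), Scel (1.51 ± 0.21), Pnpla3 (1.24 ± 0.17), Ccdc80 (0.82 ± 0.12), Ap3s1 (0.73 ± 0.09), Notch3 (0.69 ± 0.09) and Gca (0.60 ± 0.08) rose, each with an adjusted p of 0.00146 or below. Serpinf1 fell by 1.84 ± 0.29, Tnc by 1.39 ± 0.19, Smad9 by 1.25 ± 0.20, Btbd3 by 0.88 ± 0.12, Sned1 by 0.86 ± 0.14, Jade2 by 0.78 ± 0.10, Ppef2 by 0.78 ± 0.12 and Sorbs3 by 0.47 ± 0.08. Fmr1 stood 0.50 ± 0.10 higher (adjusted p = 0.0190). In TPM as deposited, 360 genes passed, 300 higher and 60 lower, so the balance of directions rests on the scaling. Without WT replicate 2 the count was 81, and without WT replicate 3 it was 269. Without double mutant replicate 4 it was 86. With endothelial, neuron and oligodendrocyte scores in the model it was 22, with the compared groups alone 46, with a replicate block 93 and with library weights 230. Leaving out the library of highest neuron score in each genotype gave 83. Day as a factor gave 127, 109 of them among the 144.

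Gene groups in the double mutant against WT held calls from signalling, matrix and astrocyte function. Of 16 SMAD-responsive targets 1 rose and 4 fell, 8 over the list alone, with a median of -0.34 (camera adjusted p = 0.00305; adjusted p = 0.419 with an estimated correlation). Acvr1 rose by 0.54 ± 0.09, 1 of 28 pathway genes, with 4 over the list alone. Kcnj10 was the 1 of 20 mature astrocyte markers that rose, 3 did over the list alone, and the list's median was 0.17 (camera adjusted p = 0.00376; adjusted p = 0.721 with an estimated correlation). Slc6a9 rose by 0.94 ± 0.16 (SE), and the receptor Gabbr1 was at 0.37 ± 0.09 (adjusted p = 0.0520). The transmitter and ion list had 2 calls, 4 over the list alone and a median of 0.15 (camera adjusted p = 0.00450; adjusted p = 0.578 with an estimated correlation). Among 29 matrix genes Adamts5 rose by 0.48 ± 0.10, Tnc fell, and Adamts9 fell by 0.88 ± 0.19. Of them 5 passed over the list alone, and Timp3 was at 0.61 ± 0.16 (adjusted p = 0.0782). Of 22 reactive genes Aspg fell by 1.00 ± 0.20 (adjusted p = 0.0192), 4 passed over the list alone, and Osmr was at -0.89 ± 0.23. The median was -0.50 (camera adjusted p = 1.29e-05; adjusted p = 0.419 with an estimated correlation). All 24 cholesterol genes stood higher with a median of 0.46 and 0 passing (camera adjusted p = 2.20e-09; adjusted p = 0.442 with an estimated correlation). Hmgcs1 was at 0.69 ± 0.26. Endothelial markers had a median of -1.01, 0 passing and 13 over the list alone (camera adjusted p = 8.06e-11; adjusted p = 0.419 with an estimated correlation). Flt1 was at -1.27 ± 0.37 and Egfl7 at -1.30 ± 0.39. Chrdl1 was at 0.61 ± 0.20 (adjusted p = 0.175), Gfap at 0.21 ± 0.35, Gpc6 at 0.10 ± 0.09, Bmp6 at -0.37 ± 0.26 and Bmp4 at 0.18 ± 0.67. Fmr1 lost its call without WT replicate 2 or 4 or double mutant replicate 1, 2 or 3, and Adamts5 without WT replicate 2 or double mutant replicate 3 or 4. Aspg and Adamts9 lost theirs without WT replicate 2 or 4 or double mutant replicate 3 or 4. All 4 also lost it with the compared groups alone, cell-type scores in the model, or the libraries of highest neuron score left out. Adamts5, Aspg and Adamts9 lost it with a replicate block too, and Adamts5 with a mean TPM of at least 5 or day as a factor. Of 31 genes named as passing, 11 kept their call in each of 14 alternatives and 19 fits without 1 library: Pmepa1, Sdc3, Chil1, Scube1, Ap3s1, Notch3, Scel, Myoc, Atoh8, Id3 and Tnc.

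The remaining lists were read for all comparisons, and no member of a list given here passed over all genes in the comparison named. In Fmr1 KO against WT, oligodendrocyte precursor markers had a median of 0.35 (camera adjusted p = 0.00977; adjusted p = 0.534 with an estimated correlation) and antigen presentation and interferon genes -0.21 (0.0115; adjusted p = 0.595 with an estimated correlation). Oxidative phosphorylation had 0.07 (0.0140; adjusted p = 0.534 with an estimated correlation) and circadian clock genes 0.18 (0.0483; adjusted p = 0.534 with an estimated correlation). Glycolysis genes (median 0.07, adjusted p = 0.0610), immediate early genes (0.00, 0.880), ribosomal protein genes (-0.04, 0.834), cell cycle genes (-0.13, 0.379), neuron markers (0.03, 0.273) and neural progenitor markers (0.13, 0.669) were not called there. Ependymal and choroid plexus markers (median -0.03, mean 0.20, tested as higher, adjusted p = 0.834) and the BMP and TGF-beta pathway genes (median 0.01, mean -0.07, tested as higher) differ in sign between the summaries. In Smad4 cKO against WT, oxidative phosphorylation stood at -0.08 and oligodendrocyte precursor markers at 0.38 (each camera adjusted p = 0.0228; adjusted p = 0.749 with an estimated correlation), and endothelial markers at -0.06 (0.690) and microglia markers at -0.04 (0.690) were not called. In the double mutant against Fmr1 KO oxidative phosphorylation stood at -0.05 (camera adjusted p = 0.0414; adjusted p = 0.971 with an estimated correlation). In the double mutant against Smad4 cKO, oligodendrocyte markers stood at 0.94 (0.000363), antigen presentation genes at -0.25 (0.00202), oxidative phosphorylation at 0.09 and ribosomal protein genes at 0.19 (each 0.00659). Mural and fibroblast markers stood at -0.44 (0.00989) and cell cycle genes at 0.22 (0.0285), and each of these lists had adjusted p = 0.547 with an estimated correlation. Transmitter and ion genes at 0.10 and neural progenitor markers at 0.42 followed there (each 0.0224; adjusted p = 0.547 and adjusted p = 0.524 with an estimated correlation). Cholesterol genes stood at 0.12 (0.0424; adjusted p = 0.811 with an estimated correlation) and oligodendrocyte precursor markers at 0.42 (0.0493; adjusted p = 0.726 with an estimated correlation). In the double mutant against WT, oligodendrocyte markers stood at 1.26 (6.16e-05; adjusted p = 0.691 with an estimated correlation). Oligodendrocyte precursor markers, Olig2 among them at 1.03 ± 0.37 (SE), stood at 0.60 (0.000208; adjusted p = 0.502 with an estimated correlation) and synapse regulators at 0.08 (0.0222; adjusted p = 0.419 with an estimated correlation). The clock gene Per2 was at 0.64 ± 0.16 there (adjusted p = 0.0717), 1 of 2 clock genes that passed over the list alone.

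The effects of the Fmr1 label with Smad4 labelled intact and with Smad4 labelled deleted were also compared across genes. Pearson's r was 0.322 and Spearman's rho 0.370 over 15049 genes, with a permutation p of 0.0198 from 100 draws of the labels within each Smad4 genotype. The permutation p was 0.0594 with day as a number and 0.139 with a replicate block. Jade2 (-0.60 and -0.63), Aspg (-0.71 and -0.71), C4b (-1.05 and -1.01), Flt1 (-1.33 and -1.33) and Fmr1 (0.57 and 0.62) had close values in both. Of them Fmr1 and Jade2 passed, in the comparison with Smad4 labelled deleted. These genes were picked after their values were seen. Others lay further apart, such as Kcnj10 and Adamts5, with interactions of -0.39 ± 0.20 and -0.21 ± 0.13 (SE) that did not pass. Whether the differences by the Fmr1 label were turned back in the double mutant was read on 100 genes. These had the smallest p in Fmr1 KO against WT, in a fit without the Smad4 cKO libraries. In the double mutant against Fmr1 KO 73% of them had the opposite sign, where simulated groups without any effect gave a median of 90% (permutation p = 0.85), because both comparisons share the Fmr1 KO libraries. The median ratio of the changes was -0.12, against -0.43 in the drawn groups.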

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

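Tests chosen only after the result was seen were the share of non-astrocyte nuclei, both tests of neuron markers by day, and list scores of the interaction by linear model, as were postnatal day as a factor and the fits without the libraries of highest neuron score.

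Lower endothelial markers in the libraries labelled Fmr1 KO are the first pattern weighed. The most abundant of the 15 was Cldn5, at 193 ± 113 scaled TPM (SD, n = 4) in WT, 175 ± 56.8 (n = 6) in Smad4 cKO, 81.8 ± 47.5 (n = 5) in Fmr1 KO and 84.5 ± 24.3 (n = 4) in the double mutant. Slc2a1 is the 1 member also in the glycolysis list. Tables argue against scaling, since the median change in Fmr1 KO against WT was -1.113 in TPM as deposited. They also argue against a lower share of all non-astrocyte nuclei, since oligodendrocyte markers had a median of 0.618 and their scores moved apart from the endothelial ones (exact permutation within Smad4 genotypes, p = 0.00960, and p = 0.00522 for neuron markers). Oligodendrocyte markers did not themselves differ beyond their spread. Exact permutation gave p = 0.444 in Fmr1 KO against WT and p = 0.132 over all libraries within Smad4 genotypes. Microglia markers did not move apart over all libraries (p = 0.15 by the same permutation). Over the 19 libraries the 15 markers rose and fell together within genotypes, with a mean pairwise correlation of 0.79, against at most 0.121 in random gene sets of like abundance. Estimated correlations of other lists ran from 0.043 for BMP and TGF-beta pathway genes to 0.944 for oligodendrocyte markers. Cholesterol genes, a pathway and not a cell type, had 0.629. Genes of a pathway can thus also rise and fall together, so the correlation does not separate the possible sources. RNA of endothelial nuclei that passed the SOX9 and NEUN sort in varying amounts is a candidate source. A vascular difference of the Fmr1 genotype stays open and was not tested. WT replicate 3 lay among the libraries labelled Fmr1 KO at -0.56. The mean Rn45s share differed by the same label, at 29.2% in WT, 26.1% in Smad4 cKO, 19.7% in Fmr1 KO and 18.6% in the double mutant. Whether it bears on these markers was not tested.

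Neuron markers followed the postnatal day, with a mean score of -0.40 ± 0.40 (SD, n = 8) on day 26, 0.52 ± 0.41 (n = 9) on day 27 and -0.76 ± 0.25 (n = 2) on day 28. Of the day 28 libraries 2 of 2 lay below all day 27 libraries. Both are labelled Fmr1 intact. Among the 4 day 27 and 2 day 28 libraries of that label such an order has a chance of 0.0667. That is the smallest these numbers allow, so the test could not exclude a steady change with age. Over all 9 day 27 libraries the chance is 0.0182, but these include libraries labelled Fmr1 KO. Day 27 differed from the other days within genotypes by exact permutation (p = 0.000185), but this contrast was picked from the same scores and adds no support for a cause. A difference between collection days or sorts stays open as well. Collection and sort dates are not given in the sources used here.

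Fmr1 was higher in 9 of 9 libraries labelled Fmr1 KO than in any other. Reads shared with Fxr1 and Fxr2 are argued against, as their largest change was 0.15 of that of Fmr1. So are scaling, with changes of 0.643 and 0.707 in TPM as deposited, and a shift of the whole region. Over 25 genes within 5 Mb the median change was 0.004 in Fmr1 KO against WT and 0.047 in the double mutant against Smad4 cKO, with upper quartiles of 0.237 and 0.407, below the changes of Fmr1. Of the 25, 10 were higher in both comparisons and 5 lower in both, and none passed. Those higher in both include Slitrk2 (0.237 and 0.248), Aff2 (0.271 and 0.490), Ids (0.152 and 0.342), Tmem185a (0.127 and 0.202) and Vma21 (0.414 and 0.504). F8a, at 0.619 and 0.479, is the 1 gene above Fmr1 itself, in Fmr1 KO against WT, so a shift of some neighbours stays open. A transcript that the insertion allele may still make stays open, and so does an exchange of the Fmr1 labels of all libraries, as gene-level TPM holds no value that separates them.

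Libraries were also compared with others of their group, and 23 of 344 tests placed 1 library far from the rest (6.7%). Chance flags about 1 in 20 groups, and 22 of the 23 are given here. In scaled TPM, the double mutant had replicate 4 at 7.60 for Adamts5 (others 6.11 to 6.24), and replicate 3 at 1.32 for Bmp6 (2.15 to 2.23) and at 31 for Chrdl1 (25.1 to 25.4). Its replicate 1 was at 22.4 for Ldlrad4 (17.4 to 17.8), 86.4 for Map2 (80.8 to 81.5), 9.59 for Nap1l3 (13.9 to 14.3) and 36.2 for Smad4 (30.8 to 30.9). Fmr1 KO had replicate 3 at 36.7 for Ap3s1 (45.4 to 49.0) and 14.9 for Nap1l3 (11.2 to 12.1), and replicate 5 at 13.8 for Fam206a (19 to 20). WT had replicate 4 at 14.1 for Chrdl1 (17.8 to 18.4) and 234 for Id3 (435 to 451), replicate 3 at 20.1 for Notch3 (23.6 to 24.2), and replicate 2 at 10.6 for Rnf144b (6.53 to 7.07) and 138 for Slc25a18 (162 to 163). Smad4 cKO had replicate 6 at 13.6 for Grasp (7.09 to 8.36), replicate 2 at 19.8 for Id1 (39.3 to 57.3) and replicate 1 at 60.5 for Slc25a18 (89.5 to 98.7). Among list scores, synapse regulators were at 0.23 in Fmr1 KO replicate 2 (-0.11 to -0.02) and glycolysis genes at 0.14 in WT replicate 1 (-0.06 to -0.03). FMRP-bound transcripts were at 0.23 in double mutant replicate 3 (-0.01 to 0.02) and oligodendrocyte markers at -0.74 in double mutant replicate 1 (1.06 to 1.40).

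The Smad4 effect of 5 gene lists differed between Fmr1 backgrounds by camera on the interaction, and 0 lists did with an estimated correlation. Neuron markers had a median interaction of 0.57, from -0.49 in libraries labelled Fmr1 intact to 0.05 in libraries labelled Fmr1 KO (camera adjusted p = 0.00142, and 0.840 with an estimated correlation). Cell cycle genes had 0.33, from -0.21 to 0.19 (0.00908; adjusted p = 0.840 with an estimated correlation) and ribosomal protein genes 0.18, from -0.11 to 0.04 (0.00913; adjusted p = 0.840 with an estimated correlation). Cholesterol genes had -0.16, from 0.28 to 0.17 (0.0124; adjusted p = 0.872 with an estimated correlation) and reactive astrocyte genes 0.25, from -0.23 to 0.04 (0.0200; adjusted p = 0.840 with an estimated correlation). Neuron markers follow the day, and day 27 held 2 of 4 WT, 2 of 6 Smad4 cKO, 3 of 5 Fmr1 KO and 2 of 4 double mutant libraries. With day as a factor their median interaction was 0.55, and that of their score 0.52 ± 0.34 (SE). None of the 5 list scores reached an unadjusted p under 0.05 in a linear model, with day or without.

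Other splits of the same libraries were tested for every count of genes. In Smad4 cKO against WT, 2 of 100 splits, the real split included, gave as many as the 118 genes, and the highest other gave 1343. For the double mutant only the real split reached the count against Fmr1 KO (61, 1 of 100, highest other 11). The same held against Smad4 cKO (3, 1 of 100, highest other 1) and against WT (144, 1 of 35, highest other 20). Such ranks argue against chance for these counts but cannot exclude it, as the splits are few and several comparisons were made. The count of 3 is not stable, at 0 without any 1 of the 4 double mutant replicates, with a replicate block, the compared groups alone, cell-type scores in the model, or the libraries of highest neuron score left out. It was 1 without Smad4 cKO replicate 2. For Fmr1 KO against WT (100 of 100, highest other 192) and the interaction (99 of 99, highest other 54) the real count was 0, which every split reaches, so splits say nothing of chance there. The split with 1343 genes set the 4 day 27 libraries against 6 of other days and points to a structure of the samples by day; with day as a factor 119 genes passed in that comparison, 102 of them among the 118. The split with 192 genes had 4 of 4 day 27 libraries in 1 arm and 1 of 5 in the other.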

How the results depend on the processing

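Tests chosen only after the result was seen were cell-type scores as covariates, day as a factor, leaving out the libraries of highest neuron score, and leaving out small RNA genes.

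For each change given here the cause was not tested, except that a threshold of 0.1 passes more genes by itself. Whether fewer libraries alone moved a count was not tested either, and some counts rose with fewer libraries. At an adjusted p under 0.1, Fmr1 KO against WT had 8 genes, Smad4 cKO against WT 187 and the double mutant against WT 285. Without the libraries of highest neuron score the counts were 84, 64, 24 (double mutant against Fmr1 KO), 0 (against Smad4 cKO) and 83 (against WT). A replicate block gave 63 in Smad4 cKO against WT, then 21, 0 and 93, and the compared groups alone gave 62, 20, 0 and 46. Cell-type scores gave 36, 0 and 22 in the double mutant against Fmr1 KO, Smad4 cKO and WT. Against WT the double mutant had 360 in TPM as deposited and 230 with library weights. Without 1 library each, counts ranged from 0 to 164 in Fmr1 KO against WT, and 80 to 131 in Smad4 cKO against WT. They ranged from 27 to 62, 0 to 4 and 81 to 269 in the double mutant against Fmr1 KO, Smad4 cKO and WT, and were 0 in each fit of the interaction. Low values came without WT replicate 2, Fmr1 KO replicate 5 and any double mutant replicate, and both 164 and 269 without WT replicate 3. Replicate numbers do not pair the libraries: 5 of 25 same-number pairs correlated above 0.1, with a median of -0.002. The correlation of Smad4 effects was 0.186 (permutation p = 0.188) with a block and that of Fmr1 effects 0.226 (p = 0.139), and with day as a number the latter was 0.334 (p = 0.0594).

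Signs of 8 genes reversed in some fit, none of them passing in either. In TPM as deposited Smad4 was at 0.039 (Fmr1 KO against WT), 0.012, 0.075 and 0.051 (double mutant against Fmr1 KO, Smad4 cKO and WT) and Gpc6 at 0.078 (double mutant against Smad4 cKO). With cell-type scores Smad4 was at 0.064, 0.001, 0.132 and 0.065 in the same order, with Bmp6 at 0.242 and Id1 at 0.495 (Fmr1 KO against WT). Bmp6 was at 0.09 (Smad4 cKO against WT), Gpc6 at 0.03 and 0.037 (double mutant against Fmr1 KO and Smad4 cKO) and Bmp4 at -0.96 (double mutant against WT). Without the libraries of highest neuron score Bmp4 was at 0.546 and Id3 at 0.007 (Fmr1 KO against WT), Bmp4 at 0.019 (Smad4 cKO against WT), and Smad4 at 0.003, Bmp6 at 0.043 and Gpc6 at 0.022 (double mutant against Fmr1 KO) and Gpc6 at 0.035 (against Smad4 cKO). With a block Smad4 was at 0.004 (Smad4 cKO against WT), Gpc6 at 0.024 (double mutant against Smad4 cKO), and Fmr1 at -0.026 and Smad4 at -0.035 (interaction). In Smad4 cKO against WT Bmp6 was at 0.046 with quantile normalization and Bmp4 at 0.048 with library weights. With day as a number Gpc6 was at 0.008 (double mutant against Smad4 cKO) and Bmp4 at -0.169 (against WT), and with day as a factor Smad4 at 0.021 and Gpc6 at 0.012 (against Smad4 cKO) and Bmp4 at -0.037 (against WT).

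Without 1 library each, sign also depended on the library. Ranges were -0.085 to 0.005 for Smad4 and -0.515 to 0.439 for Bmp4 (Fmr1 KO against WT). They were -0.084 to 0.005 for Smad4, -0.322 to 0.047 for Bmp6 and -0.025 to 0.191 for Chrdl1 (Smad4 cKO against WT). They were -0.066 to 0.018 for Smad4, -0.261 to 0.719 for Bmp4, -0.121 to 0.008 for Gpc6 and -0.176 to 0.055 for Chrdl1 (double mutant against Fmr1 KO). Others were -0.065 to 0.018 for Smad4, -0.082 to 0.806 for Bmp4 and -0.092 to 0.037 for Gpc6 (double mutant against Smad4 cKO), -0.286 to 0.601 for Bmp4 (double mutant against WT), and -0.034 to 0.143 for Fmr1 and -0.025 to 0.075 for Smad4 (interaction).

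Pseudocounts of 0.1 and 0.5, no filter and no variance trend reversed no named gene. Of 51 lists called at the preset correlation, 51 lost the call with an estimated correlation, 13 with a mean TPM of at least 5, 12 with quantile normalization, 11 with a block, 9 in TPM as deposited, and 3 each with no filter and a pseudocount of 0.1; none reversed. Without small RNA genes 128 passed in Smad4 cKO against WT, 65, 2 and 159 in the double mutant against Fmr1 KO, Smad4 cKO and WT. TPM gives no counts, so what read depth limits is unknown.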

Other observations

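The test of SMAD targets against other cell types was chosen only after the result was seen.

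SMAD-responsive targets differed in both directions by the Smad4 label, with Pmepa1 and Skil higher and Id3, Atoh8, Smad9 and Msx2 lower in Smad4 cKO than in WT. RNA of endothelial cells, neurons and oligodendrocytes is argued against as the source. With their scores in the model the called members kept a median of 0.99 of their change (lowest 0.90). In Smad4 cKO against WT the scores of these cell types differed by -0.05, -0.49 and 0.32 in that order. None differed beyond its spread (exact permutation p = 0.89, 0.271 and 0.671). The model had little difference to take out, so the kept share alone is a weak test. Scores of the remaining cell types were not in the model, so their RNA was not tested. Whether Smad4 acts on these genes itself stays open; binding of SMAD4 at them, not measured here, would test it.

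The correlation of Smad4 effects across genes, r = 0.259, was exceeded by few draws of random labels (permutation p = 0.0297, highest draw 0.290), and that of Fmr1 effects, r = 0.322, likewise (permutation p = 0.0198, highest draw 0.514). Neither passed in each alternative: the permutation p was 0.188 and 0.139 with a replicate block, and 0.0594 for Fmr1 effects with day as a number. The first principal components of the 19 libraries held 16.4%, 10.1%, 8.3% and 7.2% of the variance.

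Day 27 libraries differed from the other days in other marker scores besides neurons, with means of -0.64 against 0.57 for microglia (exact permutation within genotypes, adjusted p = 0.0133), -0.13 against 0.12 for mature astrocytes (0.0125) and -0.21 against 0.19 for mural cells and fibroblasts (0.0446). The contrast of day 27 was picked from the neuron scores of the same libraries, so these values add no support for a cause.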
